A study of Caenorhabditis elegans with 2 samples.

How the data were processed

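Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole Caenorhabditis elegans L4 larvae, per the labels at 48 hours after synchronisation from starved L1 animals. The strain carries ctbp-1, the worm homologue of the C-terminal binding protein family of transcriptional corepressors, tagged with GFP at its own locus on X, and the immunoprecipitation used an antibody against GFP. There were 2 biological replicates in 1 group, and no second condition was analysed here, so no comparison between conditions was made.

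The values were 8 peak lists on genome build ce11, per the labels. Each replicate had its own ranked list of peaks and its own thresholded list, and 4 lists described the series as a whole, including a conservative thresholded list of 2775 peaks. Per the file listings deposited with the samples, the series-level lists derive from the alignments of both replicates and a further file that the listings do not describe, and the thresholded lists also derive from another undescribed file. The aligner, the peak caller, their versions and the number of mapped reads are not given in the sources used here, so the depth behind the peaks is unknown and no interval in the text covers it. The signal value of each peak is the authors' own, deposited with the peak, and was used to describe, rank or filter peaks within a list. The score column of the deposited lists is the scaled irreproducible discovery rate (IDR), a measure of how alike the ranks of a peak are in paired lists. The deposited ranked lists also give the -log10 of the global IDR. Every peak of the deposited thresholded lists had a global IDR of 0.01 or less in its ranked list. The p-value column of the deposited lists holds -1.0 in every row and was not used. In the series-level ranked lists, 16 columns with the values of single inputs were not used. The signal tracks named in the file listings were not used here.

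Coordinates were counted from 1. The reference was the C. elegans genome WBcel235, which has the coordinates of ce11, with the Ensembl release 115 annotation. All peak ends lay within the chromosome lengths of that sequence. The background held 19973 protein-coding genes on nuclear chromosomes with 29314 distinct transcript 5' ends. In this annotation 205 of these genes share 97 gene names, and all loci of a name counted as members of a list, so values for near-identical copies such as histone or small heat shock genes are uncertain.

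The series-level thresholded list was the main list, and its mitochondrial peaks were counted in the test by chromosome and left out of the tests of location, genes and motifs. Replicate lists were compared by an overlap of at least 1 bp against 1000 shuffles of one list within chromosomes, and signal values were compared at summit pairs within 100 bp. Peaks per chromosome were tested with a two-sided exact binomial test against the share of sequence. Summits were placed in promoter windows (1000 bp upstream to 250 bp downstream of a protein-coding 5' end), then exons, introns or intergenic sequence, and compared with 1000 shuffles of summits within chromosomes. For 26 gene lists, the share of genes with a promoter summit was tested with a two-sided Fisher's exact test against all other protein-coding genes. For 20 motifs, windows of 75 bp on either side of the summit were compared with windows of the same width centred 400 bp away on a randomly chosen side, with a two-sided exact McNemar test. Each family of tests was adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Intervals of shares are 95% Wilson intervals, which cover counting error over genes or peaks and treat these as independent, although neighbouring genes and peaks are not.

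The tests, gene lists, motifs and 34 alternative settings were fixed before the data were examined, and 14 alternatives were added afterwards. The alternatives changed the peak list, left out each replicate in turn, changed the promoter window, the background or the motif window, or left out peaks of particular kinds. The genes named in the text follow a rule that was also fixed beforehand. It takes ctbp-1 and 4 genes linked to it in earlier genetic work, the genes with a promoter summit among the 20 peaks of largest signal, the 3 members with the strongest promoter peak from each list above the background, and up to 2 members from each list below it. The 3 shared peaks whose ranks differed most between replicates were not named by gene.

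The tests of gene lists, chromosomes, location, motifs and replicate overlap were tested on simulated data. A 5-fold higher rate planted in the ribosomal protein list was called in 100 of 100 simulated gene sets, drawn over 19973 genes, and 0.2% of the tests of other lists passed the threshold. An X share raised by 1.2 times was called in 91 of 100 simulated peak lists. A planted promoter excess and a planted motif were each called in 20 of 20 simulations. The motif simulation drew summit and flank windows with the same base frequencies. It does not cover the difference in G and C content between the real windows. A planted overlap of replicate lists was called in 20 of 20 simulations of 1000 peaks, and 10% of 20 pairs without one also passed the threshold. The tests of noncoding genes and of X against autosomes were not simulated. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and blastn 2.17.0 were used.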

Results

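The data describe where GFP-tagged CTBP-1 was recovered on the genome of L4 larvae. The series-level thresholded list held 2927 peaks, of which 2911 lay on nuclear chromosomes and 16 on mitochondrial DNA. The thresholded list of replicate 1 held 1404 peaks and that of replicate 2 held 1715. Peaks of the series-level list had a median width of 364 bp and a median signal value of 85.98 in the authors' units. A width of exactly 364 bp was shared by 2633 of the 2927 peaks, so it does not describe the extent of single bound sites. Whole animals were used, so a peak carries no information on the tissue in which the DNA was bound.

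The first question was how far both replicates gave the same sites. Of the replicate 1 peaks, 1067 (76%) overlapped a replicate 2 peak, against 1.70% ± 0.319 (SD of 1000 shuffles) for shuffled peaks. Of the replicate 2 peaks, 1095 (63.8%) overlapped a replicate 1 peak, against 1.38% ± 0.267 for shuffled peaks. Both two-sided permutation tests gave p = 0.001, the smallest that 1000 shuffles can give. No row was identical in both thresholded lists. At 979 peaks with paired summits, the signal values of the replicates had a Spearman correlation of 0.773 and a Pearson correlation of 0.976 across peaks, which are not independent replicates. On nuclear peaks alone, the Pearson correlation was 0.889. The median log2 difference of replicate 2 from replicate 1 was 0.03, with an SD of 0.41 over peaks. The 3 paired peaks whose relative ranks differed most had replicate 1 summits at V 10537114, III 13068510 and V 5846037. At the first of these the signal was 7.05 in replicate 1 and 79.1 in replicate 2. Of the series-level peaks, 1064 (36.4%) overlapped a thresholded peak of each replicate and 1036 (35.4%) overlapped none of either.

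**Figure D1:**
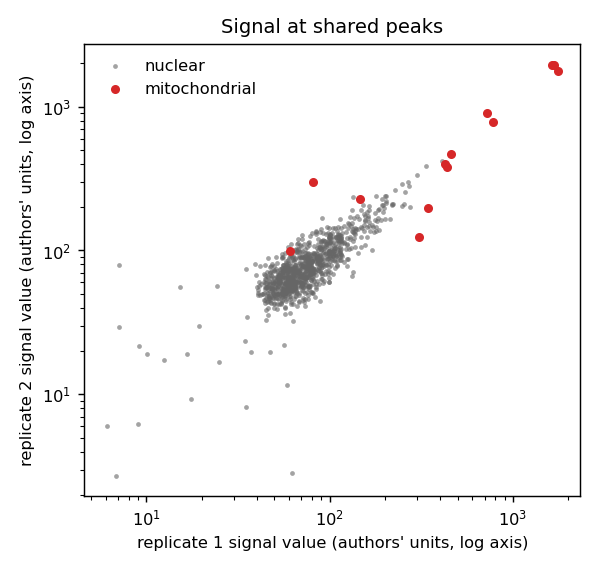
Signal values of replicate 1 (x axis) and replicate 2 (y axis), in the authors' units on log axes, at 979 peaks with paired summits in both replicates' own thresholded lists. Each point is 1 peak, with mitochondrial peaks in red, and the Spearman correlation over all points was 0.773.

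The strongest peaks fell into mitochondrial DNA and a small set of nuclear sites. Of the 20 peaks with the largest signal, 11 were mitochondrial and 9 nuclear. The strongest nuclear peak had its summit at III 3867565, 289 bp upstream of the 5' end of rpl-3, which encodes a large-subunit ribosomal protein. Its signal was 832.3 in the series-level list, 411.4 in replicate 1 and 418.0 in replicate 2. The reference sequence around this summit (III 3867545 to 3867585) is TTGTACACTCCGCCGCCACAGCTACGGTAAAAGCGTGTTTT. The next nuclear peak (III 10759245, signal 718.7) lay 62 bp upstream of tasp-1, which encodes a threonine aspartase, and gave 335.6 and 388.6 in replicates 1 and 2. The sequence there (III 10759225 to 10759265) is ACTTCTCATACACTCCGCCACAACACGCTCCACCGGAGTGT. A peak at II 11759478 (signal 631.5) lay 167 bp upstream of F44E5.4, an Hsp70 family gene whose divergent neighbour F44E5.5 is a close copy, so reads may not be assigned uniquely there. Further promoter peaks among the 20 lay 151 bp upstream of cdc-48.1, an AAA ATPase (signal 546.2), 703 bp upstream of nspc-17, a member of a repeated gene family (528.3), and 585 bp upstream of tag-340 (492.1). The remaining 3 nuclear peaks among the 20 lay between protein-coding genes, with summits at V 1151497 (signal 576.9, inside the noncoding gene linc-128), X 11094198 (565.6) and X 4209280 (485.8).

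Chromosomes differed in their number of peaks for their length. Chromosome III held 17.6% of the peaks (516 peaks, 95% interval 16.3 to 19.1) against 13.7% of the sequence, with an adjusted p of 9.08e-09 in the two-sided exact binomial test. X held 21.4% (627 peaks, 19.97 to 22.9) against 17.7% of the sequence (adjusted exact p = 3.65e-07), and chromosome I held 17.3% against 15.03% (adjusted exact p = 0.000744). Chromosome V held fewer peaks, 14.4% against 20.9% (adjusted exact p = 8.73e-19), and so did chromosome IV, 14.3% against 17.4% (adjusted exact p = 1.02e-05). Chromosome II held 14.3% against 15.2% and did not pass the threshold (adjusted exact p = 0.190). Mitochondrial DNA held 0.547% of the peaks (16 peaks) against 0.0138% of the sequence (adjusted exact p = 1.05e-19). That share of sequence takes no account of copy number. The excess on X did not pass the threshold once peaks at tRNA, snoRNA and snRNA genes were left out, where its ratio was 1.069 (adjusted exact p = 0.129), a setting chosen after seeing the data.

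Summits were concentrated in promoters and were scarce in exons. Promoter windows held 44.8% of the 2911 nuclear summits (1303 summits, 95% interval 42.96 to 46.6) against 26.5% ± 0.830 (SD of 1000 shuffles) expected by chance. Exons held 6.01% against 21.2%, and introns held 20.4% against 27.3%. Intergenic sequence held 28.9% against 25%. Each of the 4 permutation tests gave an adjusted p of 0.001, the smallest possible. With promoter windows of 2000 bp upstream to 500 bp downstream, the intergenic excess did not pass the threshold (ratio 1.065, adjusted permutation p = 0.095). Against the 81782 nuclear ranked peaks that overlapped no thresholded peak, the promoter share was 44.8% compared with 27.2%. On X, 37% of summits lay in promoter windows, compared with 46.9% on the autosomes (Fisher's exact test, adjusted exact p = 2.13e-05). Promoter windows also make up less of X, 22.7% of its sequence against 28.03% of the autosomes, so the ratio of summits to sequence was 1.63 on X and 1.67 on the autosomes. Peaks at tRNA genes were 23.6% of the peaks on X and 5.94% to 7.86% of those on each autosome. Without them the promoter shares were 43.2% on X and 48.4% on the autosomes, which did not pass the threshold (adjusted exact p = 0.0854), and without peaks at any tRNA, snoRNA or snRNA gene they were 43.2% and 49.1% (adjusted exact p = 0.0432), settings chosen after seeing the data. Relative to sequence, X was then the higher, at 1.91 against 1.73 without peaks at tRNA genes and 1.90 against 1.75 without peaks at any of these genes. The ratios to sequence were not tested against each other.

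**Figure D2:**
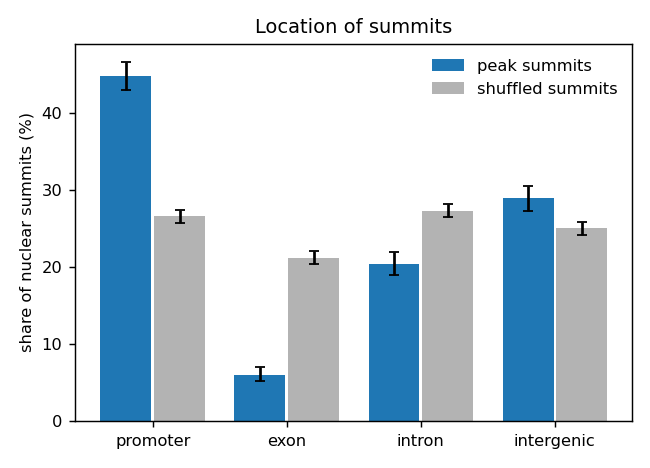
Share of the 2911 nuclear summits in each class of sequence (y axis, percent), for peak summits (blue, bars of the 95% Wilson interval) and for 1000 shuffles within chromosomes (grey, bars of 1 SD). Promoter windows held 44.8% of summits against 26.5% in the shuffles, and exons 6.01% against 21.2%.

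The next question was which genes carried a promoter summit. Of 19973 protein-coding genes, 1422 (7.12%) did. The share was 4.52% without replicate 1 and 3.78% without replicate 2, where the shorter list of the other replicate alone was used. No control coverage or expression values were used here. Differences between gene lists therefore cannot be told apart from recovery at open or highly transcribed chromatin, which was not tested. Genes of the cytosolic ribosome stood out, with 37 of 78 (47.4%, 95% interval 36.7 to 58.4) against 6.96% of other genes (Fisher's exact test, adjusted exact p = 4.05e-21). The count was 28 of 78 (35.9%) without replicate 1 and 23 of 78 (29.5%) without replicate 2. Their strongest promoter peaks were at rpl-3, at rpl-20 (IV 4750068, signal 442.1, with 203.7 and 240.8 in replicates 1 and 2), where the 5' end of Y17G9B.5 lay nearer, and at rpl-15 (IV 654911, signal 429.4, with 222.6 and 211.2). Heat shock genes had a promoter summit at 8 of 22 members (36.4%, 19.7 to 57.0, adjusted exact p = 0.000311). Without the top 5% of peaks by signal the count was 5 of 22, and the ratio to the expected share was 3.38 (adjusted exact p = 0.0446) against 5.11 in the full list. The strongest were hsp-60, the mitochondrial chaperonin (III 1619142, signal 358.8), hsp-90, the cytosolic chaperone (V 14685769, signal 283.0), whose summit lay inside the annotated gene and upstream of a transcript 5' end, and hsp-3, an endoplasmic reticulum Hsp70 (X 6092175, signal 232.6). The hsp-60 and hsp-90 peaks lay nearer to the 5' ends of other genes, 213 bp from Y22D7AL.10 against 600 bp from hsp-60 and 284 bp from C47E8.4 against 391 bp from hsp-90. With each peak given to its nearest 5' end alone, 6 of 22 heat shock genes had a peak (adjusted exact p = 0.00866), and without replicate 2 also 6 (adjusted exact p = 0.0011). The small heat shock genes among these members have close copies.

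Genes of corepressor and repressive chromatin complexes were also above the background, with 12 of 46 members (26.1%, 15.6 to 40.3, adjusted exact p = 0.000281). Their 3 strongest peaks were at lin-9 (III 8904292, signal 275.2, with 134.6 and 135.2 in replicates 1 and 2) and lin-54 (IV 13240684, signal 253.5), whose products belong to the DREAM complex, and at lin-53, a histone-binding protein gene (I 9620038, signal 192.2). The lin-54 peak lay 33 bp from the 5' end of the ribosomal gene rpl-12 and 360 bp from that of lin-54, and so counted in both lists, and the lin-53 peak lay 189 bp from nra-2 and 278 bp from lin-53. With each peak given to its nearest 5' end alone, 10 of 46 corepressor genes had a peak (adjusted exact p = 0.00337). Heterochronic genes, which time larval development, had promoter summits at 8 of 21 members (38.1%, 20.8 to 59.1, adjusted exact p = 0.000281). These included ain-1, which acts with microRNA-bound Argonautes (X 16612545, signal 239.4), lin-66 (IV 13887661, signal 160.0) and lin-28, which encodes an RNA-binding protein (I 8409970, signal 148.1), whose summit lay inside the annotated gene, 50 bp upstream of a transcript 5' end. Panneuronal genes had promoter summits at 10 of 28 members (35.7%, 20.7 to 54.2, adjusted exact p = 8.43e-05), among them unc-108, a Rab2 gene (I 3824444, signal 236.1), with its summit inside the annotated gene and 503 bp upstream of a transcript 5' end, the guanine nucleotide exchange factor gene rgef-1 (V 9561988, signal 193.1) and the liprin gene syd-2 (X 10555583, signal 142.0). The syd-2 peak passed the threshold in the list of replicate 1 and not in that of replicate 2, although its signal was 62.5 in replicate 1 and 70.7 in replicate 2. Without replicate 2, the counts were 7 corepressor, 4 heterochronic and 6 panneuronal genes, and without replicate 1 they were 8, 5 and 7. All 6 passed the threshold, with the highest adjusted exact p at 0.0269 for the heterochronic genes without replicate 2.

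Chemoreceptor, C-type lectin and neuropeptide genes lay below the background. Of 1364 chemoreceptor genes, 12 (0.880%, 95% interval 0.504 to 1.53) had a promoter summit (adjusted exact p = 2.32e-28), the strongest at sre-23 (signal 171.9) and srh-269 (136.9). Of 240 C-type lectin genes, 2 did (0.833%, 0.229 to 2.99, adjusted exact p = 5.39e-05), clec-126 (signal 121.8) and clec-57 (72.7). These 4 peaks all lay within 200 bp of a tRNA, snoRNA or snRNA gene, and without peaks at such genes the counts were 8 chemoreceptor and 0 lectin genes, a setting chosen after seeing the data. The clec-57 peak did not pass the threshold in the list of replicate 1, and the 5' end of srz-97 lay nearer to it. Without replicate 2, 6 chemoreceptor genes and 1 lectin gene had a promoter summit, and both lists passed the threshold. Of 142 neuropeptide and insulin genes, 3 did (2.11%, 0.721 to 6.03, adjusted exact p = 0.0437), the strongest at ins-39 (X 1345059, signal 205.4) and nlp-15 (74.4), whose peak passed the threshold in neither replicate's own list. The neuropeptide result passed the threshold under 4 of its 14 alternatives.

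The other lists did not pass the threshold. Promoter summits were present at 6 of 30 Wnt signalling genes (adjusted exact p = 0.0504), 6 of 40 bHLH (0.134), 7 of 49 zinc finger (0.168) and 7 of 97 homeobox (0.998) transcription factor genes, and 16 of 274 nuclear hormone receptor genes (0.690). Among markers of tissues the adjusted exact p was 0.0613 for body muscle (6 of 32 genes), 0.935 for pharynx (1 of 28), 0.953 for germline (2 of 45), and 1 for intestine (2 of 30) and for hypodermis and seam (2 of 34). Sperm protein genes had 2 of 79 (adjusted exact p = 0.233), cuticle collagens 6 of 177 (0.130), histones 5 of 81 (1), ligand-gated channels 9 of 109 (0.788), axon guidance genes 4 of 34 (0.490), insulin signalling genes 4 of 28 (0.233), and lipases and desaturases 1 of 43 (0.563). For zinc finger genes the ratio to the expected share was 2.007 in the full list, 0.451 without replicate 1 and 1.620 without replicate 2. For ligand-gated channels it was 1.160, 0.609 and 0.243, and neither list passed the threshold in these settings. The cuticle collagens moved with the setting, from below the background in the conservative list (4 of 177, adjusted exact p = 0.0418) and the upper 0.5 of the list by signal (1 of 177, 0.0378) to 17 of 177 (9.60%) against 6.52% of other genes with nearest 5' ends (0.247).

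**Figure D3:**
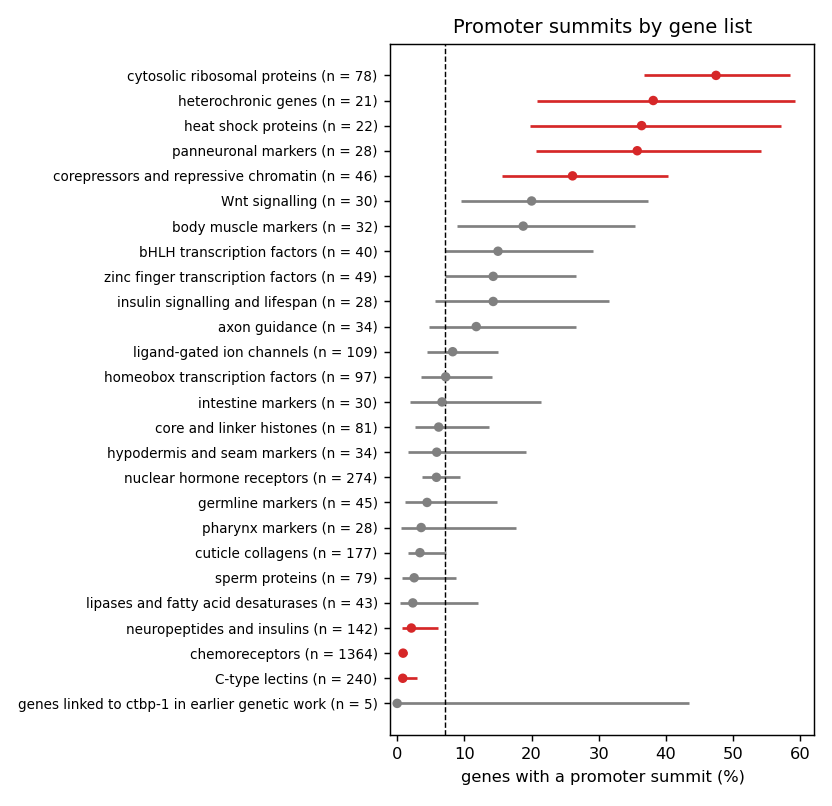
Share of genes with a promoter summit (x axis, percent) in each of 26 gene lists, with 95% Wilson intervals over genes. Red marks lists past an adjusted p of 0.05 and the dashed line the 7.12% of all protein-coding genes. Ribosomal proteins lie highest at 47.4%.

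Neither ctbp-1 nor the 4 genes linked to it in earlier genetic work had a promoter summit in the series-level thresholded list (Fisher's exact test, adjusted exact p = 1), a list of 5 genes, too short for the test to show a depletion. At ctbp-1 itself (X 5862708 to 5873347) the nearest thresholded summit lay 15250 bp from the annotated 5' end, outside the gene. The distance was 11470 bp for ttx-3, a homeobox gene, 17675 bp for the acetylcholine-gated channel gene acc-4, 22447 bp for the SOX gene egl-13 and 140786 bp for the lipase gene lips-7. The promoter windows of ctbp-1, acc-4, egl-13 and lips-7 held ranked peaks that missed the threshold, the strongest with signal values of 29.8, 51.9, 23.5 and 20.6. The ranked list held 85313 peaks, with a median signal of 18.2 and widths summing to 31001850 bp. Ranked peaks in promoter windows are therefore no evidence of binding, and their rate at other genes was not compared.

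Sequence under the summits was richer in G and C than its flanks, 46.1% against 35.4%. The motif tests did not adjust for this difference, and base composition was examined only for GAGAGA. For the other motifs, higher or lower, a difference in sites cannot be told apart from the difference in base composition. The GAGA repeat (GAGAGA) occurred within 75 bp of 31.3% of summits and in 9.03% of flanks, a ratio of 3.46 (exact McNemar test, adjusted exact p = 1.83e-99). The site of KLF and SP factors (CCRCCC) occurred at 14.3% against 5.39% (adjusted exact p = 6.11e-29), the E2F or DREAM site (TTSSCGC) at 10.2% against 4.397% (adjusted exact p = 3.78e-17) and the E-box CACGTG at 4.603% against 2.40% (adjusted exact p = 8.99e-06). The CREB site was rare but also higher, 1.37% against 0.481% (adjusted exact p = 0.000892), but did not pass the threshold in the conservative list (ratio 1.682, adjusted exact p = 0.0963) or with windows of 150 bp on either side (ratio 1.37, adjusted exact p = 0.192). Other motifs were less frequent at summits. They were the trans-splice acceptor (6.11% against 16.5%), the homeobox core (9.0% against 18.8%), runs of A or T (9.52% against 18.4%), the TATA box (7.49% against 16.1%), and the GATA (20.955% against 28.1%), SOX (3.92% against 7.56%) and forkhead (3.40% against 5.46%) sites. All 7 passed the threshold, with the highest adjusted p at 0.000286 for the forkhead site. With flanks 800 bp away the forkhead site did not pass it (ratio 0.839, adjusted exact p = 0.269). The E-box CACCTG bound by ZEB-like factors (3.06% against 3.33%, adjusted exact p = 0.653) and the THAP domain core (17.1% against 16.3%, adjusted exact p = 0.555) did not pass it. Nor did the ETS (adjusted exact p = 0.0731), POU (0.159), bZIP or PAR (0.167), nuclear receptor (0.617), AP-1 (0.653) and T-box (1) sites. In the list of replicate 1 alone, 3 motifs rather than 5 were higher at summits, and the E-box CACGTG and the CREB site missed the threshold.

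**Figure D4:**
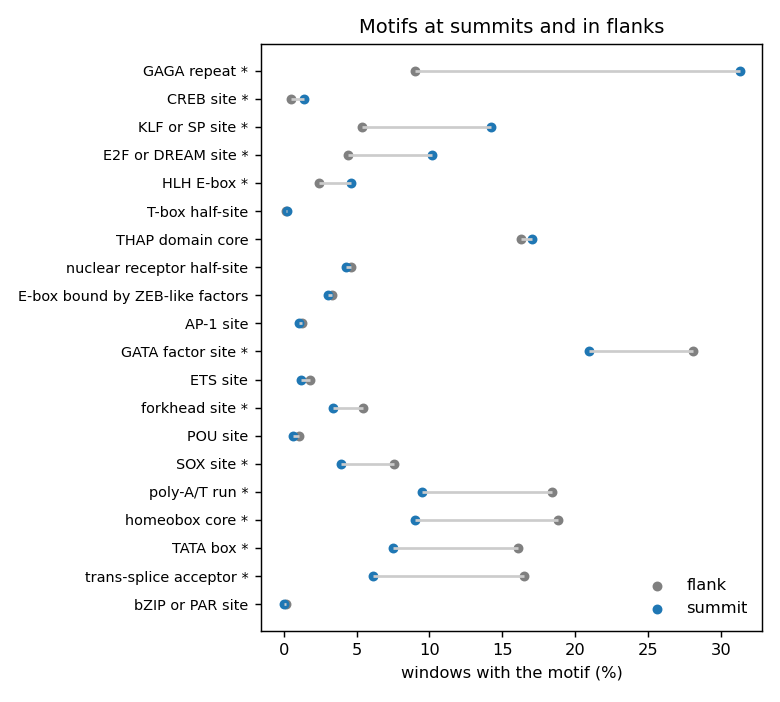
Share of windows with each of 20 motifs (x axis, percent) at summits (blue) and in flanks 400 bp away (grey), over 2911 nuclear peaks. An asterisk marks motifs past an adjusted p of 0.05, and GAGAGA occurred at 31.3% of summits against 9.03% of flanks.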

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

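Of the tests in this part, the one on the share of mitochondrial peaks past the threshold was chosen after the result was seen. The 16 mitochondrial peaks stood out because the tests of location, genes and motifs did not use them, although 11 of them were among the 20 with the largest signal. Their median signal was 775.3 against 85.8 for nuclear peaks, and they covered 34.9% of mitochondrial DNA. The first lay at M 4568 to 4921 (signal 3703, with 1665 and 1958 in replicates 1 and 2). Reads from nuclear copies of mitochondrial sequence were argued against, since 1 of the 16 peaks had a nuclear match of at least 90% identity over 50 bp or more. Many copies of mitochondrial DNA in the extract remain a possible explanation. In both replicates 100% of ranked mitochondrial peaks passed the threshold, against 3.44% and 3.65% of nuclear ones. In the series-level list 94.1% did, against 3.41%. Such shares would follow from large signals of any cause, so they do not bear on copy number. Many copies cannot be told apart from binding, because no control coverage was used here, and no biological explanation was tested.

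The series-level ranked list also held 28 peaks past the IDR threshold that the thresholded list leaves out. The thresholded lists derive in part from a file that the listings do not describe, and whether it is a list of excluded regions is not given in the sources used here, so the reason for the omission is open. They were singled out because the main lists do not hold them. As added peaks they entered only alternative settings of the gene list test and of the counts at noncoding genes. Comparisons with ranked peaks outside the thresholded list did not set them apart. The strongest was at X 15810925 to 15811288, with a signal of 629.5.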

How the results depend on the processing

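The settings that left out peaks beside a stronger peak or at tRNA or other small RNA genes, kept 1 locus per gene name, added the left-out ranked peaks or used nuclear peaks alone were chosen after seeing the data. Among the overlaps, the correlation, the promoter excess and the counts of chromosomes, lists and motifs, 76 of 78 alternative values stayed on the same side of the threshold or close to the value reported. The Spearman correlation moved from 0.773 to 0.5495 when all peaks shared in the ranked lists were used, and the cause was not tested. The number of motifs higher at summits was 3 without replicate 2 and 5 without replicate 1, against 5 in the full list; replicate 1's own list is shorter. The overlap of replicate 1 peaks ranged from 67.7% to 79.8%, and the promoter ratio from 1.345 to 1.82 around 1.69. Lists above the background numbered 5 to 7 and those below it 2 to 4 over 14 alternatives. Ribosomal protein genes were 5.11 to 8.36 times their expected share and corepressor genes 3.03 to 4.73 times. Of single lists, motifs, chromosomes, classes and the promoter share of X, 593 values kept their call, 18 lost it and 19 gained it, with no change of direction past the threshold. Of the losses, 10 were in the neuropeptide list. Wnt signalling passed under 3 alternatives, body muscle under 4, cuticle collagens (lower) under 2, the ETS, POU and bZIP or PAR sites (lower) under 3 each and the ZEB-like E-box (lower) under 1. The number of mapped reads is unknown, so what depth limits cannot be stated.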

Other observations

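The classes of noncoding genes, the gene name families and the features of the GAGA repeat and of X were chosen for testing after the data were seen. Peaks were frequent at small RNA genes. Summits lay within 200 bp of 332 of the 612 nuclear tRNA genes (54.2%), and 309 peaks lay there against 8.73 ± 2.93 (SD) in 1000 shuffles. For snoRNA genes 79 peaks were counted against 5.41, for snRNA genes 25 against 1.72, and for the spliced leader RNA genes 10 against 0.390. The spliced leader gene sls-1.10 is labelled snRNA in this annotation, so the snRNA and spliced leader counts may hold the same peaks. Pseudogenes had fewer peaks than shuffles gave, 23 against 106.3. Each of these 5 permutation tests gave p = 0.001, the smallest possible with 1000 shuffles, and an adjusted p of 0.00133. For lincRNA genes 22 peaks were counted against 9.26 (adjusted permutation p = 0.00133), for microRNA genes 10 against 3.68 (adjusted permutation p = 0.00571) and for rRNA genes 0 against 0.425 (adjusted permutation p = 1). The count for rRNA genes depends on ranked peaks past the IDR threshold that the thresholded list leaves out, for a reason not given in the sources used here, where an exclusion list was not ruled out. With these added it was 2 against 0.476 (adjusted permutation p = 0.092), from peaks at V 17122874 to 17123237 (signal 109.1) and V 17129341 to 17129704 (92.6), and the other 7 classes kept their calls. The median signal was 103.4 at tRNA genes and 84.0 at other nuclear peaks.

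Among 175 families of genes with a shared name stem, 11 were above the background and 6 below it at an adjusted p of 0.05 in Fisher's exact test. Beyond the ribosomal and hsp families, promoter summits were present at 18 of 47 lin genes (adjusted exact p = 7.24e-08) and 20 of 94 unc genes (0.000204), stems that name mutant phenotypes rather than a shared function. They were present at 9 of 19 sec genes of the secretory pathway (adjusted exact p = 9.63e-05) and 11 of 31 vps genes of vesicle sorting (0.000179). They were also present at 8 of 29 dnj chaperone genes (0.0105), 6 of 20 mdt genes of the Mediator complex (0.0229), 6 of 20 vha genes of the vacuolar ATPase (0.0229) and 5 of 15 cox genes of cytochrome oxidase (0.0307). The fbxa genes were below the background, with 1 of 170 (adjusted exact p = 0.00204). As for the gene lists, open or highly transcribed chromatin was not tested as a cause.

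Reads shared between identical copies were weighed as a source of the tRNA peaks. The share with a summit was 38.5% among 143 tRNA genes of unique sequence and 59.1% among 469 with identical copies, a ratio of 0.6512 (95% bootstrap interval 0.512 to 0.804). The lower bound lay only just above the limit set before the test, so this argues narrowly against shared reads as the whole cause. A part of the excess may come from them. Any summit within 200 bp counted, so a unique gene could be counted through a neighbouring gene. Genes with near-identical copies were not set apart. Proximity to protein-coding promoters was argued against, since 241 of the peaks lay outside promoter windows, 20.08 times the upper bound of 12 in shuffles. Open or highly transcribed chromatin was not tested.

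The tRNA genes bear on X, which holds 276 of them (45.1%). Without peaks within 200 bp of a tRNA gene, X had 1.036 times its share of peaks (95% interval 0.954 to 1.12), against 1.21 with them, so a candidate explanation of the X excess is the number of tRNA genes there. A second hypothesis was that X peaks include sites of the motif through which the dosage compensation complex is recruited to X. Its core GCGCAGGG occurred within 75 bp of 2.392% of X summits (15 of 627) and 0.175% of autosomal summits (4 of 2284, Fisher's exact test, adjusted exact p = 5.60e-07), and in 0 X flanks. The peak at ins-39 is one example, with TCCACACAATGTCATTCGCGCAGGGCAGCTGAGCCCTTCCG at X 1345039 to 1345079. The motif may mark a few X peaks, and 15 are too few to account for the excess.

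The GAGA repeat at summits was set against its sequence context. Among other orderings of 3 A and 3 G, leaving out AGAGAG, the highest ratio of summits to flanks was 2.135, below the 95% bootstrap interval of 3.06 to 3.95 for GAGAGA. Without peaks holding an alternating run of 12 bp or more the ratio was 3.236, and outside promoter windows it was 3.781. Base composition, alternating runs of 12 bp or more and location in these promoter windows were therefore each argued against as the whole cause. The windows cover annotated protein-coding 5' ends alone. Promoter sequence elsewhere and open chromatin were not examined and were not argued against. Shorter or imperfect GA tracts were not examined and were not argued against. A sequence preference of the bound sites is a hypothesis that the same data raised. No biological explanation was tested. The repeat occurred at 39.3% of the 728 summits of strongest signal and 23.4% of the 728 of weakest signal, and at 17.2% of summits at tRNA genes. Over 4 groups by signal, from strongest to weakest, the ratios of summits to flanks were 4.4, 2.976, 4.659 and 2.429. These ratios had no steady order with signal.

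The thresholded list held 122 peaks with a signal under 17.7, the median of ranked peaks outside that list. All 122 had a stronger thresholded peak within 400 bp, compared with 0.723% of equally weak ranked peaks that did not pass. A summit of a replicate's own thresholded list lay within 100 bp of 11.5% of them, against 62.9% of the stronger peaks.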
